A study of Mus musculus with 36 samples.

How the data were processed

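Total RNA of mouse skin was labelled with Cy3 and hybridised with a Cy5-labelled universal mouse reference, per the labels' protocols, to Agilent arrays, 3 for each of 12 groups. Per the submitters' processing notes, Agilent Feature Extraction was used, with a version not given in the sources used here. The values analysed were those of the 2 deposited value tables, with 30 and 6 arrays; scanner files were not used here. Background handling, centring, filters and the direction of the 2-dye comparison are not given in the sources used here.

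The deposited values were taken as log10 by their range, which reached from -0.982 to 6.14 in the first table and from 1.48 to 5.84 in the second, with many values at exactly 2, which is 100 on a linear scale. The log base is inferred, not stated, and every fold rests on it. Array medians near 2.9 in both tables leave open whether arrays were centred. The design fixed before the data were examined assumed log ratios, and the range and the values at 2 read as a brightness-like log10 scale. Whether the values are a brightness or a ratio put back on such a scale is not settled; limma can be used on both, so the test was kept. The value 2 is called the floor here, although 245 to 1457 values per array of the first table and 768 to 1217 of the second lie below it. Values were multiplied by the base change from log10 to log2, with no further normalization. No values were missing. Features with the same value on every array (490 and 1874) were left out, which left 41430 and 41056 for testing. Values at or near the floor may give no measured level, so differences from or to it may be understated. Since some values lie below it, the floor does not set a lower bound on the level.

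Direction was checked on features that sat at 1 repeated low value on at least 21 of 30 arrays (2357 features). Those that departed from it upward alone had the repeated value 2 in 191 of 555, and those that departed downward alone in 0 of 580. In the second table the numbers were 86 of 213 and 0 of 241. An upward departure was shared with a replicate of the group in 23.8% and with an array of another group in 11.2%, a downward one in 15% and 10.9%. The counts at 2 do not give the direction. A value built as skin minus reference plus the mean reference could give them, and so could one with the 2 dyes exchanged. Most features that departed upward alone also had a repeated value other than 2. Only the sharing bears on direction, since skin differs between groups and the reference does not, and upward departures were shared more with replicates. A higher value therefore likely means more skin RNA in the first table, which no label states. In the second table at least 5 of the 6 arrays held the repeated value, so departures could not be shared with a replicate. Its direction is assumed to be the same. A check of direction with lists of mature and embryonic markers was planned and needs gene names.

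The annotation table given, of assembly GRCm38.p6, holds no key to the feature numbers, and 0 features were named from it. Whether several features report the same transcript is not known, so features named together may not be distinct and counts of features are not counts of genes. Gene lists fixed before the data were examined were therefore not used, nor were coordinates. By the rule fixed before the data were examined, features were chosen per comparison from those past the threshold whose 3 values in one group all lay beyond the 3 of the other, by the size of the rise or fall, and since no table names the features, the 2 first in each direction are given. Features of the genotype by stage test were ranked by the change of the Tabby difference from 13.5 to 16.5 dpc.

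Groups, ages and replicates came from the labels. Back skin is spelled out for the 18.5 dpc arrays and abbreviated BS for the others, which is read the same way here, while FP is not spelled out and is kept. Descriptions of the wild-type FP samples name 16.5 dpc, and their titles, sources and ages name 18.5 dpc, which was used. The Tabby strain also carries an agouti allele that the wild-type strain lacks. The design text says samples were triplicated, and nothing says whether replicates came from separate animals, so p-values measure the spread between these arrays, which may be technical.

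Differences were tested with limma 3.58.1 in R 4.3.3, with group means of all 30 arrays of the first table (20 residual degrees of freedom) or the 6 of the second (4), eBayes and Benjamini-Hochberg adjustment, two-sided, at an adjusted p of 0.05. Genotype by stage was tested with limma's F test on 2 contrasts. Overlaps of calls were tested with Fisher's exact test, two-sided. Calls of the first table share 1 estimate of spread per feature, so features of small spread may be called in several comparisons. The numbers given as by chance take the lists as independent and may be too low. Array serial numbers in the labels of the first table step by 1 or 2 over its first 15 arrays, by 19 to the next 3 (Tabby array c of 14.5 dpc, wild-type array e and Tabby array c of FP), and by 10 to the 16.5 dpc and 2-month arrays, where they step by at most 4. The step of 4 lies between the last wild-type and the first transgenic array of 2 months. The blocks that the wide steps of 19 and 10 make are taken as batches. The run fixed before the data were examined joined the last replicate of each genotype at 13.5 dpc, 14.5 dpc and FP, which the steps bear out in FP alone.

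Replicate labels are shared between genotypes in back skin at 13.5, 14.5, 16.5 and 18.5 dpc. Arrays with the same label deviated from their group means together at 13.5 dpc (r = 0.16, 0.33 and 0.29), 14.5 dpc (0.11, 0.23 and 0.18) and 18.5 dpc (0.13, 0.23 and 0.16), over features, so these labels were taken as pairs by the rule that every r exceeds 0.1. The pairing comes from these values and no label explains it. The fit with the replicate as a block used the 2 groups compared.

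The steps were tested on simulated data with 200 changed features and the spread of each array as measured. In back skin at 16.5 dpc, with 41430 features, 87% of 2-fold and 98% of 4-fold changes were recovered with 0 false calls. At 13.5 dpc the shares were 81% and 99% with 30 false calls, in FP 82% and 99% with 30, at 14.5 dpc 77% and 96% with 6, and in transgenic skin 83% and 96% with 41. With equal spread on every array the false calls were 11 at 16.5 dpc, 14 at 13.5 dpc, 10 in FP, 6 at 14.5 dpc and 8 in transgenic skin. In the second table, with 41056 features, the shares as measured were 79% and 96% with 2 false calls.

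Alternatives fixed before the data were examined were centring on array medians, quantile normalization, a fit of the 2 groups alone, eBayes with trend and robust, array weights, leaving out the 25% of features with the smallest SD, a minimum of 1.5-fold, an adjusted p of 0.10, the replicate and the run as blocks, and leaving out each array. Leaving out features with a mean under 2.3, the first 2 replicates alone, the serial step as a block, and the replicate as a block at 13.5 and 14.5 dpc for genotype by stage were added after seeing the data.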

Results

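RNA from mouse skin was measured on 36 Agilent arrays with 2 dyes each, in 12 groups of 3 arrays. Skin RNA carried Cy3 and a reference pooled from mouse cell lines carried Cy5 on every array. Tabby mice carry a mutation of the ectodysplasin gene Eda, whose signal is needed for the first hair follicles, and were set against wild-type C57BL/6J mice. The groups were Tabby and wild-type back skin at 13.5, 14.5, 16.5 and 18.5 days post coitum (dpc), Tabby and wild-type samples marked FP at 18.5 dpc, and back skin of wild-type and EDA-A1 transgenic mice at 2 months. EDA-A1 is an isoform of the Eda product. Each pair of groups asks which transcripts differ with loss or gain of this signal, and the wild-type stages give the change with age.

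The first value table held 30 arrays and 41920 features, and the second held the 6 arrays of 18.5 dpc back skin and 42930 features. Array medians lay between 2.93 and 2.96 in the first table and between 2.87 and 2.88 in the second, on the log10 scale of the deposited values. The tables do not pair feature numbers with genes, so features are given by number, with at most 2 that rose and 2 that fell in each comparison, and neither Eda itself nor any gene group could be looked up. A higher value likely means more skin RNA in the first table, on the basis given with the processing. The second table is read the same way without such a basis. No label states the direction, and if it were turned, every rise here would be a fall and every fall a rise. Within groups of 3 arrays, correlations over features ranged from 0.961 to 0.997. The median SD between replicates was 0.063 on the log2 scale in wild-type and 0.068 in Tabby back skin at 16.5 dpc, against 0.148 and 0.168 at 13.5 dpc and 0.208 in wild-type skin at 2 months. Arrays carry no read depth, and the number of arrays limits the precision.

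Arrays grouped by stage and tissue before genotype. The first principal component of the 30 arrays held 42.8% of the variance and ordered back skin from 13.5 dpc to 2 months. The second held 17.3% and set the FP arrays apart from back skin. At 16.5 dpc the 3 Tabby arrays lay between 30.7 and 37.8 on it, above the wild-type arrays at 22.5 to 23.6.

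**Figure D1:**
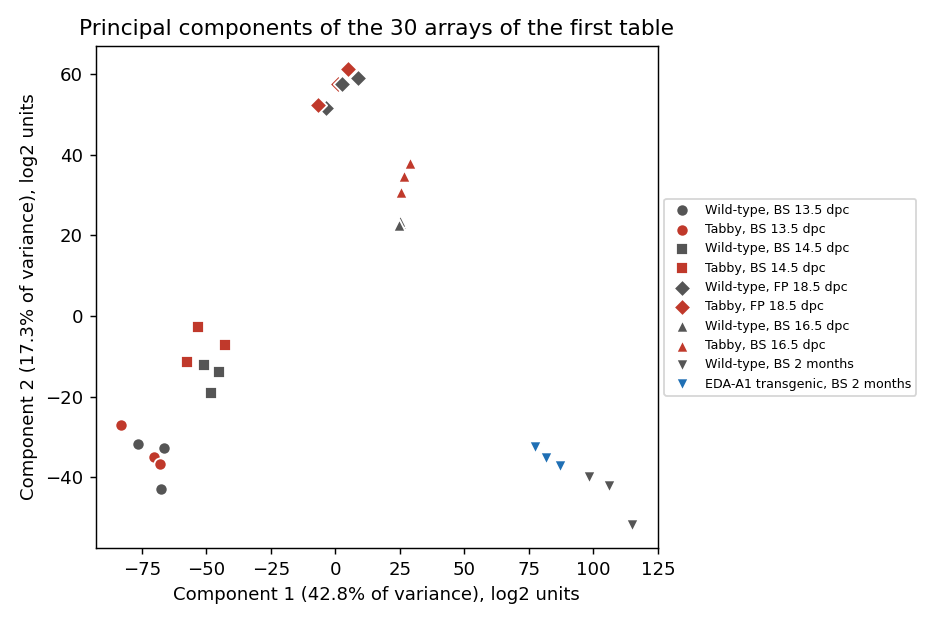
Scores of the 30 arrays of the first table on components 1 (42.8% of variance) and 2 (17.3%), in log2 units, with 1 point per array, color for genotype and shape for stage or tissue (BS, back skin). Back skin runs from 13.5 dpc at the left to 2 months at the right, and the 6 FP arrays lie at the top.

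Few features differed between Tabby and wild-type back skin at 13.5 dpc. Feature 37231 fell by 1.44 ± 0.14 (SE, n = 3 per group) on the log2 scale, a 2.72-fold lower level, with an adjusted p of 1.18e-05 in limma. Feature 37787 fell by 1.27 ± 0.14, with an adjusted p of 3.51e-05. Features 26468 and 15706 rose by 0.82 ± 0.08 and 0.76 ± 0.10, from a wild-type mean of 2.11 for both, near the floor of 2, so their folds may be understated. Both lay at 2.01 on every array of the other groups, which narrows these errors: in the fit of the 2 groups alone the SEs were 0.14 and 0.17. Of 41430 features tested in limma, 7 passed an adjusted p of 0.05, with 2 higher and 5 lower. At an unadjusted p of 0.05, 2473 passed against 2072 expected by chance, and 9% of features had groups without overlap, where chance gives 10%. With the replicate as a block in a fit of the 2 groups, limma called 0 features, with 2613 at an unadjusted p of 0.05. Without the block that fit called 0, with 1353. Leaving out wild-type array 3 gave 11, and leaving out features with a mean under 2.3 gave 0 higher and 4 lower, with 2035 features at an unadjusted p of 0.05.

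At 14.5 dpc 68 features differed in Tabby back skin, 50 higher and 18 lower, a balance that rests on single arrays. Feature 38928 rose by 2.46 ± 0.38 (SE, n = 3 per group), a 5.51-fold higher level, from a mean of 2.56 ± 0.287 (SD) to 3.30 ± 0.023 on the log10 scale. Feature 3350 rose by 2.36 ± 0.47. Feature 31563 fell by 1.84 ± 0.24, a 3.57-fold lower level, and feature 29602 fell by 1.70 ± 0.33, both to means below 2.2, near the floor. Their adjusted p-values in limma were 0.00526, 0.0369, 0.000876 and 0.0276. Of the 68 features, 38 were at least 2-fold higher and 8 at least 2-fold lower, with 3121 at an unadjusted p of 0.05. All 68 had groups without overlap, as had 10.2% of all features, where chance gives 10%. Tabby array c follows a wide step in the array serial numbers: with that step as a block 49 features passed (32 higher and 17 lower) and the calls of features 3350 and 29602 ended, replicates a and b alone, all before it, gave 48 (14 higher and 34 lower), and the replicate as a block in a fit of the 2 groups gave 34, against 3 without the block. Leaving out wild-type array a, which ended the call of feature 38928, gave 8 higher and 10 lower, leaving out Tabby array c gave 9 and 9, wild-type array c 13 and 26, and Tabby array a 24 and 13. The call of feature 3350 ended when any of 5 arrays was left out (adjusted p from 0.0726 to 0.181), and that of feature 29602 with any of 4 (0.0511 to 0.228).

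Back skin at 16.5 dpc held the largest number of Tabby differences past an adjusted p of 0.05 among the 5 stages and tissues compared. Back skin at 18.5 dpc was fitted on 6 arrays alone, with 4 residual degrees of freedom, so its count is not on a like basis. At an unadjusted p of 0.05 in limma it had 4300 features. Feature 6058 had a 6.95-fold lower level in Tabby, falling from a mean of 4.55 ± 0.040 (SD, n = 3) to 3.70 ± 0.025 on the log10 scale. Feature 21881 had a 6.27-fold lower level, falling from 3.82 ± 0.033 to 3.02 ± 0.025. Feature 33411 had a 4.75-fold higher level, with a log2 difference of 2.25 ± 0.37 (SE), and feature 23670 a 4.66-fold higher level, with 2.22 ± 0.37, from a wild-type mean of 2.11 near the floor. The adjusted p-values in limma were 0.000288 and 0.000286 for the features that fell and 0.00125 for both that rose. Of 41430 features 798 passed, 329 higher and 469 lower, with 173 at least 2-fold higher and 55 at least 2-fold lower, and 4234 at an unadjusted p of 0.05. Groups did not overlap for 797 of the 798, and for 36% of all features, where chance gives 10%. The count changed with the way the spread was estimated, and these arrays varied less than the others. The fit of the 2 groups alone, which also changes the degrees of freedom, called 7535 features, and array weights gave 8906. Why the counts rose was not tested. Leaving out wild-type array 1, 2 or 3 gave 397, 454 and 449, and leaving out Tabby array 1, 2 or 3 gave 571, 407 and 371.

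**Figure D2:**
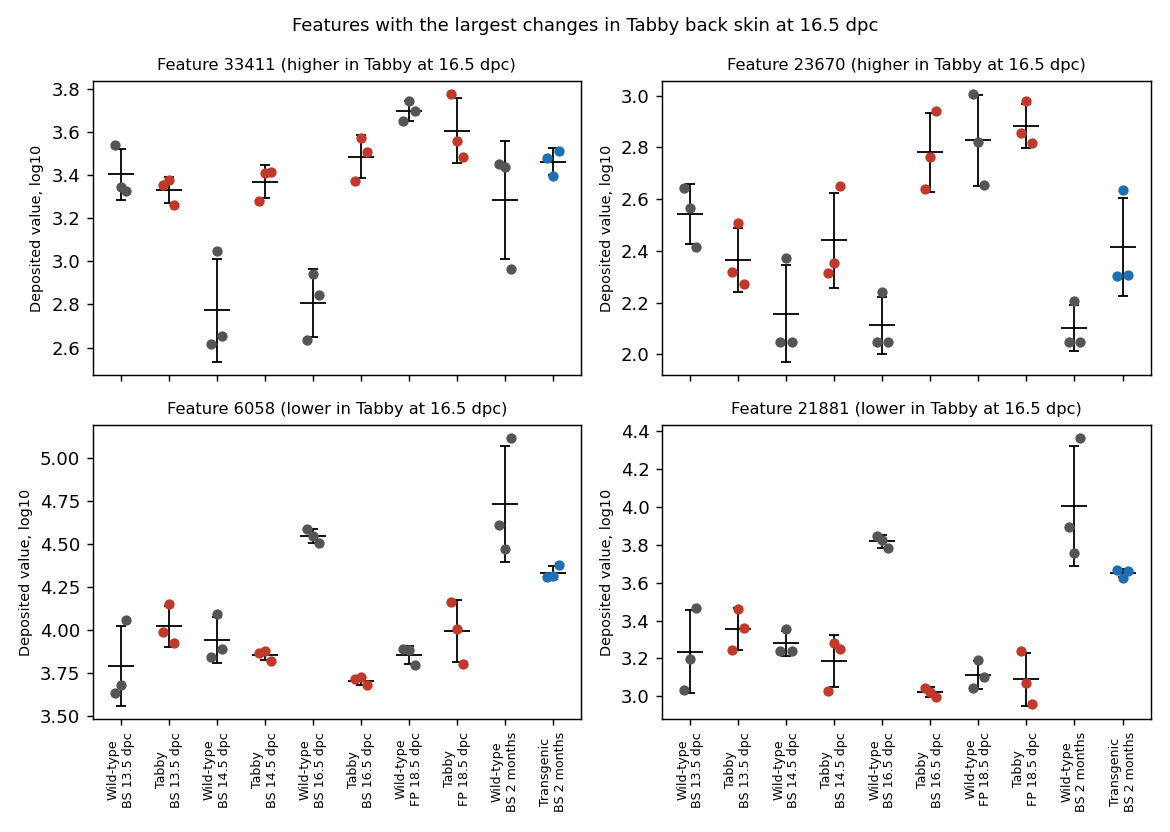
Deposited log10 values of features 33411, 23670, 6058 and 21881 on each array of the first table, with 1 point per array, a bar at the mean of 3 arrays and whiskers of 1 SD. At 16.5 dpc the 3 Tabby arrays lie above the 3 wild-type arrays for features 33411 and 23670 and below them for features 6058 and 21881.

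Most features called higher in Tabby at 14.5 dpc were also called higher at 16.5 dpc. Of the 50 called higher at 14.5 dpc and the 329 at 16.5 dpc, 43 were shared, where 0.397 would be by chance (Fisher's exact test, p = 2.73e-84, adjusted p = 3.28e-83 over 12 tests, across features, which are not independent replicates). Among features that fell, 5 of 18 were shared, against 0.204 by chance (adjusted p = 5.52e-06 in Fisher's exact test). Of the 5 features lower at 13.5 dpc, 3 were also called lower at 14.5 dpc (adjusted p = 4.13e-09 in Fisher's exact test), and both features lower in FP were also called lower at 16.5 dpc (adjusted p = 0.000384). These overlaps end in the fits of the 2 groups alone, where limma called 0 features at 13.5 dpc and in FP (1353 and 1384 at an unadjusted p of 0.05), and with the replicate block 0 were called at 13.5 dpc (2613). With the 2 groups of each stage fitted alone, 14.5 and 16.5 dpc shared 1 higher and 1 lower call, of the 3 then called at 14.5 dpc. The 173 features at least 2-fold higher at 16.5 dpc had a median log2 difference of 0.93 at 14.5 dpc, where 170 of the 173 were higher in Tabby, and of -0.20 at 13.5 dpc and -0.14 in FP. In transgenic skin at 2 months it was 0.32, with 153 of the 173 higher, the same way as in Tabby. The set means put most of this on wild-type replicate 6, at 3.17 on the log10 scale. The other wild-type arrays, at 3.42, lay within the 3.41 to 3.48 of the transgenic arrays. The mean level of the set was 2.98 ± 0.090 (SD, n = 3) in wild-type and 3.28 ± 0.086 in Tabby at 14.5 dpc, and 3.00 ± 0.045 and 3.45 ± 0.079 at 16.5 dpc, on the log10 scale. In wild-type skin at 13.5 dpc it was 3.32 ± 0.062, so that the wild-type groups at 14.5 and 16.5 dpc were the low ones. The 55 features at least 2-fold lower at 16.5 dpc had medians of -0.12 at 14.5 dpc and 0.08 at 13.5 dpc. Across all features the Tabby differences at 14.5 and 16.5 dpc had a correlation of 0.26, over features, which are not independent replicates.

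**Figure D3:**
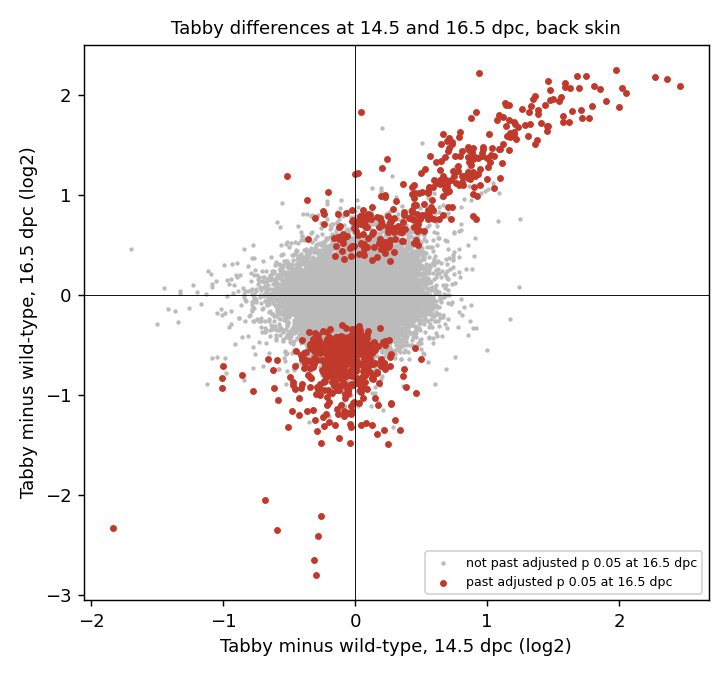
Tabby minus wild-type difference of each of 41430 features at 14.5 dpc (horizontal) and 16.5 dpc (vertical), both in log2 units, with the 798 features past an adjusted p of 0.05 at 16.5 dpc in red. Features higher in Tabby at 16.5 dpc extend along the diagonal, and most of those lower in Tabby at 16.5 dpc lie near 0 at 14.5 dpc.

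**Figure D4:**
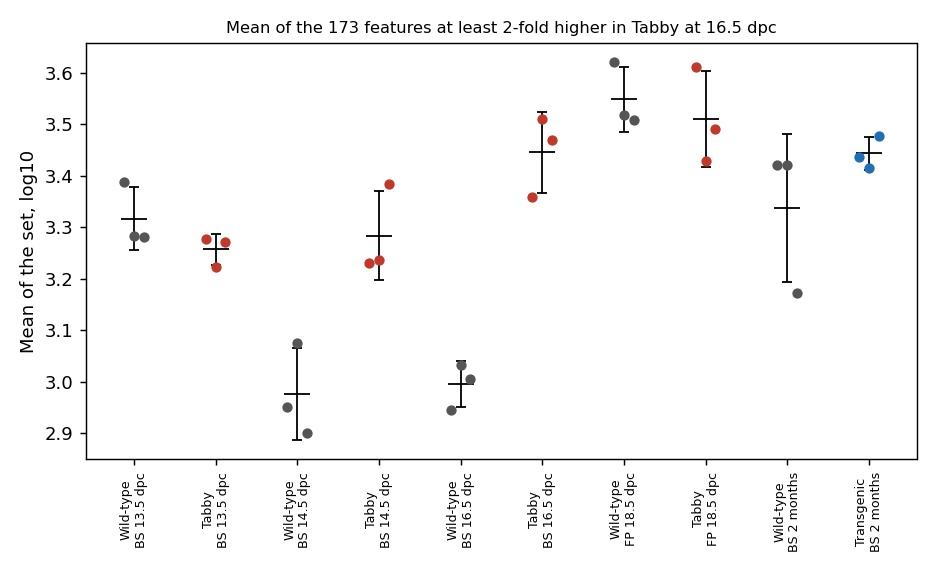
Mean log10 value of the 173 features at least 2-fold higher in Tabby at 16.5 dpc, with 1 point per array, a bar at the mean of 3 arrays and whiskers of 1 SD. The wild-type arrays at 14.5 and 16.5 dpc lie between 2.9 and 3.08, and the Tabby arrays of these stages between 3.23 and 3.51.

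The Tabby difference itself changed between 13.5, 14.5 and 16.5 dpc for some features. Feature 39134 differed by -0.72, 1.75 and 2.19 on the log2 scale at the 3 stages, and feature 23670 by -0.59, 0.94 and 2.22. Feature 6058 differed by 0.77, -0.30 and -2.80, and feature 21881 by 0.40, -0.31 and -2.65. In limma's F test of genotype by stage 162 features passed an adjusted p of 0.05, and 3373 an unadjusted p of 0.05, with adjusted p-values of 0.0203, 0.031, 0.0078 and 0.0119 for these 4. The difference grew more positive from 13.5 to 16.5 dpc in 88 and more negative in 74, and 139 of the 162 had their largest difference at 16.5 dpc. The 16.5 dpc arrays lie past wide steps in the serial numbers from those of the earlier stages, and at 14.5 dpc 1 of those steps parts Tabby array c from the other 5 arrays. With that step as a block 198 features passed, and with the replicate as a block at 13.5 and 14.5 dpc 196, of which 136 were among the 162. Of the 18 arrays left out in turn, 8 moved the count over 1.5 times: it was 63, 94 and 74 without wild-type 1, wild-type 2 or Tabby 2 of 13.5 dpc, 43, 95 and 90 without wild-type 1, 2 or 3 of 16.5 dpc, and 62 and 52 without Tabby 2 or 3 of 16.5 dpc.

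In the FP samples at 18.5 dpc, feature 37231, which was lower in Tabby back skin at 13.5 dpc, was lower again. It fell by 1.15 ± 0.14 (SE, n = 3 per group) on the log2 scale, with an adjusted p of 0.00159 in limma. Feature 35998 fell by 1.20 ± 0.17, a 2.29-fold lower level, from 4.32 ± 0.076 (SD) to 3.96 ± 0.075 on the log10 scale (adjusted p = 0.00573). Feature 22390 rose by 0.86 ± 0.14 (adjusted p = 0.0416). These were the 3 features that passed, with 2290 at an unadjusted p of 0.05 against 2072 expected and 7.1% of all features without overlap of the groups, where chance gives 10%. Wild-type array e and Tabby array c follow the wide step in the serial numbers; with it as a block 4 features passed, and the 4 arrays before it alone gave 8. Array weights and the fit of the 2 groups alone each called 0 features in limma, with 1414 and 1384 at an unadjusted p of 0.05; the call of feature 22390 ended when any of 5 arrays was left out (adjusted p from 0.0596 to 0.221) and that of feature 35998 without Tabby array b, and the count was 7, 1, 5 and 12 without wild-type c, Tabby b, wild-type e and Tabby c.

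Tabby back skin at 18.5 dpc, measured in the second table, had the largest changes among features called in the Tabby comparisons, both of them falls if a higher value means more skin RNA. Feature 12377 fell by 3.95 ± 0.26 (SE, n = 3 per group) on the log2 scale, a 15.4-fold lower level, from 4.19 ± 0.162 (SD) to 3.00 ± 0.047 on the log10 scale. Feature 920 fell by 3.94 ± 0.19, from 4.25 ± 0.097 to 3.06 ± 0.076, and feature 22231 rose by 0.84 ± 0.05. The adjusted p-values in limma were 0.023, 0.01 and 0.0207. Of 41056 features 6 passed, 1 higher and 5 lower, with 4300 at an unadjusted p of 0.05 against 2053 expected, and groups did not overlap for 16.5% of features, where chance gives 10%. The replicate as a block left 1 call, that of feature 920, and ended those of features 12377 and 22231. Leaving out any 1 array left 0 to 4 calls. It left 0 for every array but wild-type 3, with 3095 to 5629 features at an unadjusted p of 0.05 in those 5 limma fits. The call of feature 22231 ended with each of the 6 arrays left out. The log2 differences of features 12377 and 920 stayed between -4.24 and -3.71 and between -4.12 and -3.83 in these 6 fits. Feature numbers of this table do not match those of the first (r = 0.013 over 40630 shared numbers), so no level is set across the tables.

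Gain of EDA-A1 at 2 months went with many differences, most of them rises if a higher value means more skin RNA, and most of them falls if the direction is turned. Feature 42770 was 20.6-fold higher in transgenic skin, with a log2 difference of 4.36 ± 0.38 (SE, n = 3 per group), from 2.37 ± 0.288 (SD) to 3.68 ± 0.056 on the log10 scale. Feature 21444 was 10.1-fold higher, with a log2 difference of 3.33 ± 0.37 (SE), which ranged from 2.66 to 3.79 when 1 array was left out. Feature 21652 fell by 2.25 ± 0.22, a 4.77-fold lower level, and feature 29214 fell by 2.21 ± 0.31, from 5.13 ± 0.015 to 4.46 ± 0.341. The adjusted p-values in limma were 4.57e-08, 1.27e-06, 2.82e-07 and 2.17e-05. Of 41430 features 7088 passed, 5214 higher and 1874 lower, with 1070 at least 2-fold higher and 194 at least 2-fold lower. At an unadjusted p of 0.05, 13620 passed, and groups did not overlap for 42.8% of features, where chance gives 10%. Wild-type replicate 6 stood apart, with a correlation down to 0.961 with the other arrays of its group and 1457 values under 2, and without it 3525 features passed, 2523 higher and 1002 lower. Without transgenic array 1 or 2 the counts were 4543 and 4262, the fit of the 2 groups alone gave 1105, ending the calls of features 21444 and 29214, and array weights gave 14099. The share of higher among changed features was 73.6% as deposited, 62% with arrays centred on their medians and 58.5% after quantile normalization. All transgenic arrays follow the wild-type arrays of 2 months, after a step of 4 in the serial numbers. Array order and the transgene therefore cannot be told apart in this comparison.

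Wild-type back skin changed in more features with age than differed by genotype in any comparison here. From 13.5 to 16.5 dpc, feature 26447 rose 152-fold, from 2.59 ± 0.044 (SD, n = 3) to 4.77 ± 0.018 on the log10 scale, and feature 21444, which was also higher in transgenic skin, rose 136-fold from 2.28 ± 0.072, near the floor, so that this fold may be understated. Feature 1319 fell by 4.58 ± 0.24 (SE) on the log2 scale, to a mean of 2.10 near the floor, and feature 42488 fell by 3.94 ± 0.23. Of 41430 features 13889 passed an adjusted p of 0.05 in limma, 6327 higher and 7562 lower, with 17608 at an unadjusted p of 0.05, and groups did not overlap for 54.9% of features, where chance gives 10%. Array weights gave 21263 calls and a minimum of 1.5-fold gave 8007. The 13.5 and 16.5 dpc arrays lie in separate blocks of serial numbers, so block and stage cannot be told apart in this comparison.

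From 16.5 dpc to 2 months, feature 26447 fell by 6.85 ± 0.19 (SE, n = 3 per group) on the log2 scale, to a mean of 2.71 ± 0.184 (SD) on the log10 scale. Feature 25925 fell by 7.08 ± 0.14, a 135-fold lower level. Feature 38190 was 140-fold higher at 2 months, with a log2 difference of 7.13 ± 0.13, and feature 39202 was 89.8-fold higher, both from means below 2.3 at 16.5 dpc, near the floor. In limma 12119 features passed, 5223 higher and 6896 lower, with 15725 at an unadjusted p of 0.05, and groups did not overlap for 45.2% of features, where chance gives 10%. The adjusted p-values of these 4 features ranged from 1.45e-21 to 5.69e-13, those of the 4 features of the earlier interval from 8.65e-19 to 1.22e-12. Array weights gave 19779 calls and a minimum of 1.5-fold gave 7836.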

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

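The run test of the set that rose at 16.5 dpc was chosen after its values at 14.5 dpc had been seen, as were the draws within pairs and the test of the feature called in every Tabby comparison of the first table.

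The Tabby difference changed with stage in 162 features by limma's F test. From 13.5 to 16.5 dpc it changed by 2.9 on the log2 scale for feature 39134 and by 2.81 for feature 23670, and by -3.57 for feature 6058 and -3.05 for feature 21881. Of 100 draws of genotypes within stages, the real one included, 6 gave 162 or more features, with 531 at most, and these draws ignore the pairs of 13.5 and 14.5 dpc. With the replicate as a block at those stages 196 features passed, and 3 of 100 draws that exchanged genotypes within pairs there gave as many, with 637 at most. The shares fall on both sides of 0.05, so chance regrouping is not taken as excluded. Of the draws that ignore pairs, the 5 with as many all kept the genotypes at 16.5 dpc apart, as 16 draws did, and the rest gave at most 3.

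The 173 features at least 2-fold higher in Tabby at 16.5 dpc were weighed as the first pattern. Scaling stays open: 175 and 176 features passed the same limits with arrays centred or quantile normalized, but these left the median difference of all features at 0.002 and 0.004, so they moved too little to test it. A run effect confined to the 16.5 dpc arrays is argued against by the set's median difference at 14.5 dpc, on arrays of other blocks of serial numbers. It was 0.93, with 0.79 among the arrays before the wide step (3 wild-type and 2 Tabby) and 0.71 in replicates a and b. An effect of array order is not separated, since wild-type arrays precede Tabby arrays of the same label at both stages. They do so at 13.5 dpc too, where the median was -0.20. The set moved together from array to array within groups outside 14.5 and 16.5 dpc, with a mean pairwise correlation of 0.49 against 0.05 at the 95th percentile of 1000 random sets matched on level, which is consistent with a varying share of another tissue or cell type in the dissected skin. The random sets were not matched on spread, so a set of features that vary more between arrays may exceed them for that alone. On the 12 arrays of 13.5 dpc and FP the correlation of the set was 0.43. It was 0.20 for the 55 features that fell and 0.14 for the 173 with the largest wild-type rise to 16.5 dpc. Whether a share of another tissue differed by dissection or by an effect of the mutation stays open, as does joint regulation of the features higher in Tabby.

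The features that differed in the same direction in all Tabby comparisons of the first table, and were called in at least 2, numbered 7, 6 lower and 1 higher. A difference of the strains or a linked locus stays open for the set. In the F test 4 of the 7 changed with stage, which argues against a constant difference for those 4. A strain difference may itself change with stage, and 6 of the 7 were called in only 2 comparisons, which favours features that change. In transgenic skin 3 moved the other way by over 0.5, but that comparison, within 1 strain, does not test what differs between strains. Feature 37231 is the 1 called in all 4, with log2 differences of -1.44, -1.01, -0.93 and -1.15. For it a constant difference of the strains or a linked locus stays open as well. Its difference did not pass the F test (adjusted p = 0.569), and transgenic and wild-type skin, of 1 strain, differed by -0.10. A stable effect of the mutation itself may look the same, and no test here separates them.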

How the results depend on the processing

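All comparisons below were planned unless said to be added after seeing the data. The arrays carry no measure of signal over background here, and features near the floor limit the folds. With the 2 groups alone, limma called 0 features at 13.5 dpc (1353 at an unadjusted p of 0.05), 3 at 14.5 dpc, 7535 at 16.5 dpc, 0 in FP (1384) and 1105 in transgenic skin. Array weights gave 12 at 13.5 dpc, 8906 at 16.5 dpc, 0 in FP (1414), 14099 in transgenic skin, and 21263 and 19779 for the wild-type intervals. With the replicate block there were 0 calls at 13.5 dpc (2613), 34 at 14.5 dpc and 1 at 18.5 dpc, where the check of deviations pairs the arrays. The calls of all 4 named features at 13.5 dpc ended there, as they did in the fit of the 2 groups without the block. At 18.5 dpc the block ended the calls of 12377 and 22231, and no other call of a named feature changed with it. At 16.5 dpc, where arrays share only a number (r = -0.06, 0.21 and 0.16, 2 of 3 best with their own), the block gave 4767. No paired analysis was possible for FP and transgenic skin because the groups share fewer than 2 labels. The run as planned, which joins the last replicates, gave 5 in FP as a block, and the first 2 replicates alone, added after seeing the data, gave 8. The serial step as a block, added later, gave 49 at 14.5 dpc, 4 in FP and 198 for genotype by stage, and the replicate block at 13.5 and 14.5 dpc, added later, gave 196 for genotype by stage. A minimum of 1.5-fold gave 4065 in transgenic skin and 8007 and 7836 for the wild-type intervals, by a stricter limit. An adjusted p of 0.10 gave 121 at 14.5 dpc, 10 in FP, 319 for genotype by stage and 72 shared higher features at 14.5 and 16.5 dpc, by a looser one. Leaving out the 25% of features with the smallest SD gave 25 at 18.5 dpc, and leaving out features with a mean under 2.3, added later, gave 4 at 13.5 dpc, through the features tested. Shared calls of 14.5 and 16.5 dpc, with settings added later, fell to 1 higher and 1 lower with the 2 groups alone, and 8 lower were shared with array weights, in place of 43 and 5. Leaving out 1 array gave 7 to 11 calls at 13.5 dpc, 18 to 77 at 14.5 dpc, 371 to 571 at 16.5 dpc, 1 to 12 in FP, 3525 to 9868 in transgenic skin, 0 to 4 at 18.5 dpc (3095 to 5629 at an unadjusted p of 0.05 where 0), 11005 to 13234 and 9976 to 12965 for the wild-type intervals, and, added later, 43 to 209 for genotype by stage. Arrays that moved a count over 1.5 times, each given with its count in the report too, include wild-type 3 at 13.5 dpc (11), wild-type 1, 2 and 3 (397, 454 and 449) and Tabby 2 and 3 (407 and 371) at 16.5 dpc, and, for genotype by stage, wild-type 1 and 2 and Tabby 2 of 13.5 dpc (63, 94 and 74) and wild-type 1, 2 and 3 and Tabby 2 and 3 of 16.5 dpc (43, 95, 90, 62 and 52). Except where a sentence gives one, the cause was not tested. The other 114 counts stayed within 1.5 times, among them all under eBayes with trend and robust, and all under centring and quantile normalization, which left the median difference of all features between -0.046 and 0.012. Among values of named features under the alternatives, 367 kept their call and 61 lost it (8 at 13.5 dpc, 19 at 14.5 dpc, 14 in FP, 18 at 18.5 dpc and 2 in transgenic skin), and 0 reversed. Gene list shifts were not run without gene names. No gene means were made, so the planned fit of probes in place of them was not run either.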

Other observations

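The test of an opposite response to EDA-A1 was chosen after its result had been seen. Some features moved in opposite directions in Tabby and in transgenic skin. In the Tabby comparisons a difference of the strains is not separated from loss of the Eda signal. Feature 31563 was lower in Tabby by -1.84 at 14.5 dpc and -2.33 at 16.5 dpc, on the log2 scale with an SE of 0.24, and higher in transgenic skin at 2 months by 1.44 (adjusted p = 0.000184 in limma), or by 1.15 without wild-type replicate 6. Of the 469 features lower in Tabby at 16.5 dpc, 112 were called higher in transgenic skin, where 59.0 would be by chance (odds ratio 2.20, Fisher's exact test, p = 1.43e-11, adjusted p = 5.72e-11 over 8 tests), and without wild-type replicate 6 the number was 79 against 28.6, with an odds ratio of 3.19. The same 469 were called lower in transgenic skin in 31 against 21.2 by chance (exact p = 0.0335, adjusted p = 0.0893). Without replicate 6 that number was 15 against 11.3. Numbers in both directions thus lay above those by chance, and of all 7088 calls in transgenic skin 5214 were higher. Part of the excess of higher calls may reflect more calls in both directions, and how much is an opposite response was not tested. Of the 173 features at least 2-fold higher in Tabby, 153 were also higher in transgenic skin, but the set means put most of this on wild-type replicate 6. Its set mean was 3.17 on the log10 scale. The other 2 wild-type arrays, at 3.42, lay within the 3.41 to 3.48 of the transgenic arrays. The reverse did not hold for the 329 features higher in Tabby, of which 8 were called lower in transgenic skin against 14.9 by chance (odds ratio 0.524, exact p = 0.0811, adjusted p = 0.162), or 10 against 8.0 without replicate 6. An opposite response to gain of EDA-A1 is thus a hypothesis for features that fell alone, across ages that differ, and features are not independent replicates.

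Delayed maturation of Tabby skin was tested on the features changed at 16.5 dpc and stays open. Features lower in a delayed skin would be those that rise with age, but from 13.5 dpc to 2 months in wild-type skin, on arrays outside the comparison, the 469 lower features had a median log2 change of -0.05, below the -0.02 to 0.10 of the middle 95% of random sets matched on level. The 329 higher features, which would fall with age in that case, had a median of 0.03, within -0.04 to 0.12. Without wild-type replicate 6 the medians were -0.03 and 0.17. By the rule fixed before the data were examined, a median within the random range or of the other sign counts against delay, and both occurred. That rule is not followed here. Members went both ways, with 47.8% of the lower and 52.6% of the higher rising. Features can also rise and fall again over this interval, as feature 26447 did, so these medians do not decide.

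The many features changed in transgenic skin were weighed as the third pattern. The aberrant wild-type array, replicate 6, may account for part of the count, which was 3525 without it and 9181 and 9868 without wild-type arrays a and b. It does not account for all, since 3525 features were called without it, 3237 of them among the 7088. Leaving out transgenic array 1 or 2 also lowered the count, to 4543 and 4262. Scaling of the deposited values moved the share of higher features by at most 15.1 percentage points, which leaves its part in the excess of rises open, and the effect of the transgene stays open as well. Array order, which parts the 2 groups, was not tested and stays open too.

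The 6 arrays of each comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. Every split but the real one mixes the 2 groups on each side, so a real difference adds to its spread and lowers its count. Low counts in those splits are therefore no measure of chance alone. The real split gave 7 features at 13.5 dpc against at most 6 in another, 68 against 0 at 14.5 dpc, 798 against 1 at 16.5 dpc, 7088 against 101 in transgenic skin and 6 against 0 in back skin at 18.5 dpc. It gave 13889 against 0 from 13.5 to 16.5 dpc and 12119 against 5 from 16.5 dpc to 2 months, and in each of these 7 comparisons 1 of the 10 splits, the real one, gave as many. In FP 4 of the 10 gave 3 features or more, and 1 split gave 25, which points to a structure of these samples whose cause was not tested. That split has both arrays after the wide step in serial numbers on 1 side, and the 3 others that do so gave 7, 3 and 0; with the step as a block the real split gave 4. Among the 4 splits that part all 3 pairs, the others gave at most 2 features at 13.5 dpc and 0 at 14.5 and 18.5 dpc, and they differ in mixing genotypes on each side.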
